A study of Pseudomonas putida with 12 samples.

How the data were processed

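RNA recovered with anti-FLAG beads was sequenced from FLAG-tagged and untagged Pseudomonas putida KT2440, a soil bacterium. Hfq is an RNA chaperone that holds small RNAs and mRNAs together. Per the labels, the strain KL3 carries an hfq gene with 3 FLAG copies, and both KL3 and the untagged wild type were used for co-immunoprecipitation. The wild type is taken here as the background, since it has no tag for the antibody. Per the labels' protocols, cells grown in LB at 30 °C were collected in exponential, transition and stationary phase, lysed with glass beads, and incubated for 4 h with magnetic anti-FLAG beads that were then washed 5 times. The recovered RNA was treated with a 5′ polyphosphatase and made into libraries with a small RNA kit, with no fragmentation step. The aligner, the counting tool and their settings are not given in the sources used here. Each of the 6 combinations of strain and phase has 2 libraries. No label says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

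Per the file headers, the authors deposited raw counts, RPKM and a q-value for each pair of libraries in 1 table of 6824 transcripts on the KT2440 chromosome of 6181863 bp. Of these, 5350 are coding genes, 297 are intergenic small RNAs, 187 are antisense small RNAs, 122 are 5′ untranslated regions (UTRs), and 861 shorter and 7 longer than 1000 bases are predicted RNAs that carry no gene name. The deposited counts are whole numbers and were used as they stand. The deposited RPKM columns hold whole numbers too, so they were treated as a rounded score and entered only an alternative. The authors' 3 further RPKM sheets, for mRNAs, UTRs and small RNAs, repeat the RPKM columns cell for cell. Of the deposited q-values, the 4 that compare a wild-type with a KL3 library of the same phase were used, to count features under 0.05 in all 4. A deposited annotation table gave strand, coordinates, product and functional category. Gene symbols are those of the deposited annotation, which names 1411 coding genes, and all other genes appear under their locus tag. The reference list of gene names belongs to another strain and was not used here. The genome sequence was not used here either.

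Library totals ran from 2863198 to 8434755 counts in the wild type and from 5852032 to 14327330 in KL3. The 3 most abundant features took between 37.0 and 68.1% of a library. Because a few RNAs fill the KL3 libraries, the scaling decides what a change is relative to. Counts were scaled with TMM factors, which ranged from 0.44 to 1.95, so each log2 fold change is relative to the typical feature. With library totals in place of TMM the median log2 fold change of all tested features moved from -0.07 to -0.80 in exponential phase, from -0.18 to -2.05 in transition phase, and from -0.13 to -1.30 in stationary phase. Normalised read counts are CPM computed on the TMM-scaled library size, and can therefore exceed the raw share of a library.

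Features were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, glmQLFit, glmQLFTest, two-sided), on 6336 features that passed the count filter, in 1 fit of the 12 libraries with a mean per group. The threshold was a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of its F value. Contrasts were KL3 against wild type in each phase, their average, their dependence on phase (1 F test of both interaction terms), and the later phases against exponential phase within KL3. Shares of feature classes were compared by exact permutation of the strain labels within phases (216 arrangements, two-sided). Gene lists were tested with camera (limma 3.58.1, inter-gene correlation 0.01) on log2 CPM with a prior count of 2, adjusted over 17 lists in 3 phases. The lists held known Hfq or Crc small RNAs, housekeeping RNAs, ribosomal proteins, catabolite repression targets, amino acid transport, flagella and chemotaxis, the TCA cycle, ATP synthase, NADH dehydrogenase, terminal oxidases, iron, stress, cold shock, polyhydroxyalkanoate, porins, transposases and regulators. Lists of rRNA and tRNA found 0 named features, so settings that leave them out were not run. Where a group had 0 counts, a fold is a bound set against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio has an exact 95% interval. The bounds leave out counting error in the other group, so each is a larger fold than the exact 95% limit of the same counts, and none is a 95% limit. The intervals cover counting error only. Leaving out 1 library of a group without counts lowers a bound by construction, since the floor of 3 counts then stands over 1 library.

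The tests, the gene lists and the rule for naming features were fixed before the data were examined. In each phase the rule took features past the threshold whose KL3 libraries both lay above (or below) both wild-type libraries: the 10 coding genes and 10 noncoding RNAs with the highest log2 fold change, and the 5 lowest features. It also took the 6 features with the smallest p for the phase dependence, the 5 highest and 5 lowest coding genes of each contrast within KL3, a fixed set of Hfq-related and housekeeping RNAs and genes, and, per gene list, 2 to 4 members with the largest absolute log2 fold change. CrcY, which the rule also names, is not a name in the deposited table.

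The pipeline was tested on simulated counts with the real library sizes, with known changes in 99 features per fold size of 6264. Apart from these changes, both strains had the wild-type means of their phase. The few RNAs that fill the KL3 libraries were thus absent, so the scaling of the real data was not tested. The pipeline recovered 65.7, 66.7 and 39.4% of 2-fold changes and 92.9, 94.9 and 96.0% of 4-fold changes in exponential, transition and stationary phase. Of its calls, 3.1, 6.4 and 6.3% were false. A simulated list of 30 features raised 1.5-fold gave a camera p of 1.9e-12, and of 100 random lists 2 fell under 0.05. Simulated features varied independently, so this does not test the preset correlation on real lists, whose members may vary together. The replicates of every group differed by more than sampling noise, with chi-square per degree of freedom between 4.4 and 44.2, so no library was a copy of another. The counting kept strands apart as far as the data tell: 57 of 120 antisense RNAs that lie within a gene had more counts than that gene in at least 6 libraries. Of all features, 1572 share bases with another feature of the same strand, and a named feature that shares at least 10% of its bases is marked where its values are first given in the report.

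Alternatives were RLE size factors, library totals, no count filter, DESeq2 1.42.0, a block for the replicate number or for the culture within a strain, only the 4 libraries of a phase, a 2-fold minimum, limma on log2 RPKM with a pseudocount of 1 or 0.1 or a minimum RPKM of 1 in 2 libraries, and leaving out each library in turn. Lists were also tested with an estimated correlation and with fry. Other alternatives were added after the data were seen: without the 7 predicted RNAs of over 1000 bases, without all predicted RNAs, without features or list members that share bases with another of their strand, shares without those 7 RNAs, and 161 pairs of factors for the KL3 libraries of the later phases in the test of phase dependence. Functional categories (COG) were tested after the data were seen as well.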

Results

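RNA recovered with anti-FLAG beads was measured in 12 libraries of Pseudomonas putida KT2440, with 2 libraries each of KL3, whose RNA chaperone Hfq carries the tag, and of the untagged wild type in exponential, transition and stationary phase. The tagged strain KL3 yielded between 5852032 and 14327330 counts per library, and the untagged wild type, the background, between 2863198 and 8434755. Below, n = 2 libraries per group unless stated, values after ± are standard errors for log2 fold changes and SDs otherwise, and coordinates are on the KT2440 chromosome. Folds given as "at least" are set against 3 counts and are not 95% limits.

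Annotated small RNAs were the largest of the 5 classes in each of the 6 KL3 libraries. They took 50.3% ± 0.52 of all counts in KL3 in exponential phase, 71.98% ± 1.78 in transition phase and 58.28% ± 1.38 in stationary phase, against 5.25% ± 0.35, 13.59% ± 1.19 and 13.85% ± 3.09 in the wild type. CrcZ, which sequesters Hfq and so relieves carbon catabolite repression, alone took 18.4 to 43.69% of a KL3 library and 2.09 to 8.55% of a wild-type library. PhrS, which shares 56.5% of its bases with PP_1149, took 9.77 to 25.58% against 0.46 to 0.86%, and Psr2/CrcX took 1.33 to 10.33% against 0.12 to 1.81%. The 5′ UTRs rose from 0.23% ± 0.00 to 2.37% ± 0.09 in exponential phase, from 0.29% ± 0.01 to 1.27% ± 0.04 in transition phase and from 0.19% ± 0.02 to 0.71% ± 0.03 in stationary phase. The 7 predicted RNAs of over 1000 bases went the other way, from 78.63% ± 1.30, 64.02% ± 3.61 and 66.23% ± 7.30 in the wild type to 16.75% ± 0.87, 8.05% ± 1.78 and 19.73% ± 2.67 in KL3. Averaged over phases, small RNAs gained 49.29 points, 5′ UTRs gained 1.21 points and the 7 long RNAs fell by 54.78 points, each in 3 of 3 phases (exact permutation within phases, two-sided p = 0.0093, the smallest that 216 arrangements allow, and 0.0155 adjusted over 5 classes). Coding genes differed by 4.45 points (exact p = 0.2315, adjusted p = 0.2315) and the other predicted RNAs by -0.16 points (exact p = 0.2037, adjusted p = 0.2315). The coding class holds PP_1149, which lies wholly within PhrS, so reads of PhrS can count in both classes. Over both libraries PP_1149 had 3453676 counts in KL3 in exponential phase, where library totals were 14327330 and 9696131, and 65029 in the wild type. The coding share without PP_1149 was not computed, so its direction stays open. Without the 7 long RNAs in the denominator the coding share reversed to -33.8 points and the other predicted RNAs passed the test at -3.09 points.

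**Figure D1:**
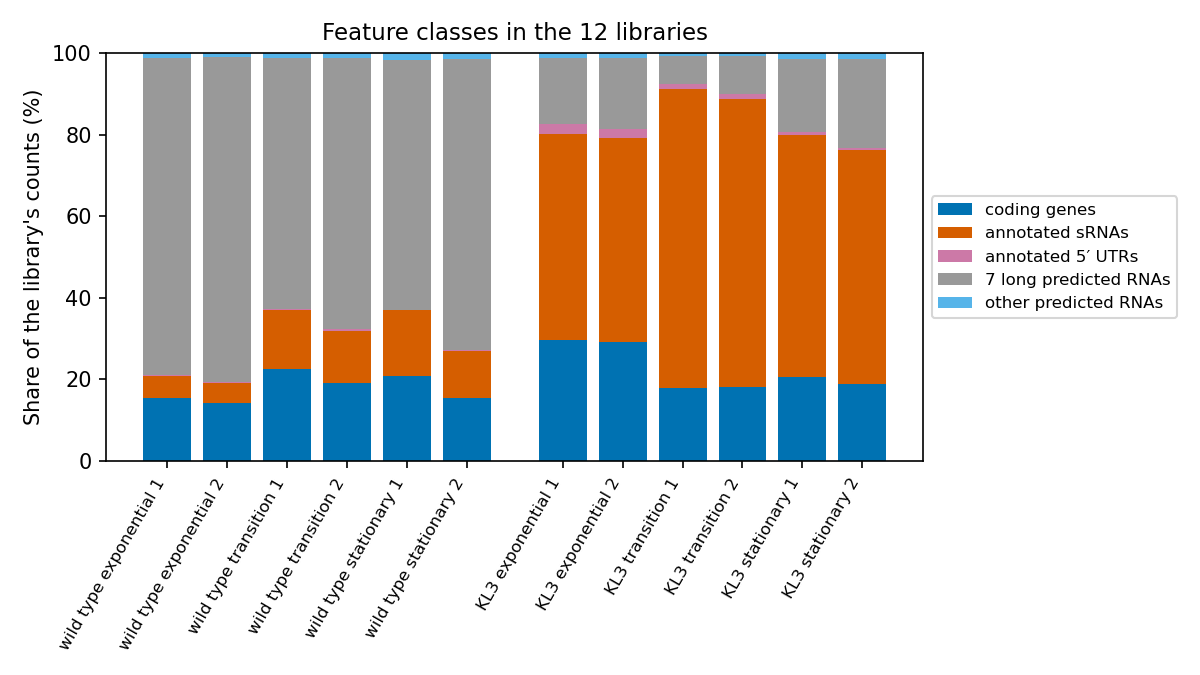
Share of counts (percent) per feature class in each library of wild type and KL3, by growth phase. Annotated small RNAs averaged 50.3 to 71.98% in KL3 and 5.25 to 13.85% in the wild type.

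The small RNAs known from other pseudomonads tested whether the tagged strain brought down Hfq partners. CrcZ (5338126 to 5338653) was 14.2-fold higher in KL3 in exponential phase (log2 fold change 3.83 ± 0.26), 20.1-fold in transition phase (4.33 ± 0.27) and 13.0-fold in stationary phase (3.70 ± 0.26). PhrS (1316226 to 1316432) was 49.4-fold, 67.4-fold and 46.7-fold higher, and Psr2/CrcX (4013153 to 4013537) was 17.8-fold, 36.5-fold and 11.3-fold higher. The iron-responsive PrrF1 rose by 4.26 ± 0.40, 3.54 ± 0.41 and 3.31 ± 0.36 on the log2 scale, the last being 2.59 without KL3_stationary replicate 2. Prrf2 rose by 1.8 ± 0.29, 1.40 ± 0.28 and 3.08 ± 0.30, but was -0.49 in transition phase with library totals. RgsA/P16 had 29 counts against 1 in exponential phase, a ratio of 27.3 (95% interval 4.52 to 1110), and rose by 4.09 ± 0.35 and 1.65 ± 0.29 in the later phases. Without wt_exponential replicate 1 it was at least 3.11-fold higher, and without wt_exponential replicate 2 the ratio was 18.0 (2.98 to 733). Its transition call was lost with log2(RPKM + 0.1) (adjusted p = 0.067), and its stationary call with library totals (0.48, adjusted p = 0.20). Spot42-like/spf/ErsA rose by 2.58 ± 0.29, 1.77 ± 0.28 and 2.15 ± 0.29, with -0.10 in transition phase under library totals. RsmY, which titrates the translational repressor Rsm, rose by 1.38 ± 0.29, 1.59 ± 0.29 and 1.18 ± 0.29, but was at -0.29 in transition phase and 0.06 in stationary phase (adjusted p = 0.84) with library totals. Its rise was lost in exponential phase with log2(RPKM + 1) (adjusted p = 0.071) or log2(RPKM + 0.1) (0.14), and in stationary phase without KL3_stationary replicate 1 (adjusted p = 0.090). RsmZ, its functional partner, went down, by -0.96 ± 0.31, -3.86 ± 0.35 and -3.91 ± 0.35, the transition value being -4.53 without KL3_transition replicate 2. The exponential call for RsmZ (adjusted p = 0.018) was lost without wt_exponential replicate 2 (0.099), KL3_exponential replicate 1 (0.11) or KL3_exponential replicate 2 (0.072). The calls that library totals ended were also lost in the 3 RPKM settings (adjusted p from 0.22 to 0.98). Of the 9 small RNAs of the list, 8 were higher and 1 lower in each phase, over all features and adjusted over the list alone, with medians of 3.83, 3.54 and 3.08 (camera adjusted p = 0.00064 in each phase, and adjusted p = 0.13 with an estimated correlation in each).

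Of 4 housekeeping RNAs, 3 were lower in KL3 in each phase, and RnpB/P28 was lower in stationary phase alone. The 6S RNA (6S/SsrS), which binds RNA polymerase, fell by 2.72 ± 0.24, 2.79 ± 0.24 and 3.65 ± 0.25 on the log2 scale across the 3 phases, and the signal recognition particle RNA (SRP) fell by 2.77 ± 0.24, 2.72 ± 0.25 and 3.99 ± 0.27. The tmRNA SsrA_tmRNA, which rescues stalled ribosomes, fell by 0.99 ± 0.24, 1.35 ± 0.24 and 2.29 ± 0.25. RnpB/P28, the RNA of RNase P, was at -0.21 ± 0.32 (adjusted p = 0.62) and -0.34 ± 0.32 (adjusted p = 0.39) and fell by 1.46 ± 0.32 in stationary phase (adjusted p = 0.0013). Its transition value depended on the wild-type library kept. RnpB/P28 passed as lower without wt_transition replicate 1, but stood at 0.38 without wt_transition replicate 2. Of these 4 RNAs, 3, 3 and 4 were lower, over all features and adjusted over the list alone. Their list passed in exponential phase (median -1.85, camera adjusted p = 0.044, adjusted p = 0.41 with an estimated correlation) and stationary phase (median -2.97, adjusted p = 0.0029, adjusted p = 0.28 with an estimated correlation), not in transition phase (median -2.03, adjusted p = 0.078). The exponential call was lost with library totals (0.096) and without wt_exponential replicate 1 (0.054), wt_stationary replicate 1 (0.050), wt_stationary replicate 2 (0.050) or KL3_exponential replicate 1 (0.055), while the transition call was gained without wt_transition replicate 1 (0.023).

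**Figure D2:**
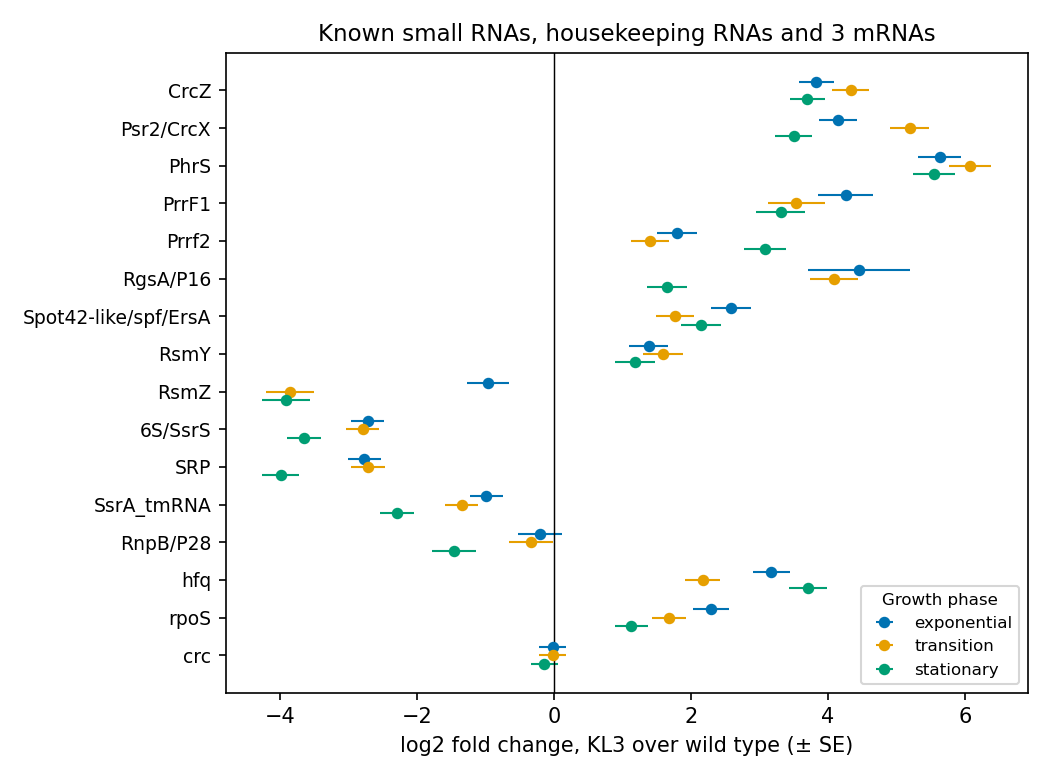
Log2 fold change of KL3 over wild type, with standard error, for the known small RNAs, the housekeeping RNAs, hfq, crc and rpoS in each phase. CrcZ lies between 3.70 and 4.33 and 6S/SsrS between -3.65 and -2.72.

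The mRNA of hfq itself (5564255 to 5564515), the tagged gene, was 9.02-fold higher in exponential phase, from a normalised read count of 127 ± 27.4 to 1140 ± 115. It was 4.5-fold higher in transition phase and 13.1-fold higher in stationary phase (log2 fold changes 3.17 ± 0.27, 2.17 ± 0.26 and 3.71 ± 0.28), though with library totals the transition value was 0.34 (adjusted p = 0.27). The strains differ at this gene, and all 12 libraries are of precipitated RNA. A changed level of the tagged mRNA therefore cannot be told apart from its recovery with Hfq. The mRNA of crc, the partner of Hfq in catabolite repression, was at -0.02 ± 0.20, -0.02 ± 0.20 and -0.14 ± 0.20 (adjusted p = 0.94, 0.93 and 0.61). With library totals crc was at -0.76, -1.90 and -1.31, beside medians of all features of -0.80, -2.05 and -1.30. The mRNA of rpoS, the stationary-phase sigma factor, rose by 2.29 ± 0.26, 1.68 ± 0.25 and 1.13 ± 0.24, but was at -0.22 in transition phase and -0.02 in stationary phase with library totals. These 2 calls and that of hfq in transition phase were also lost in the 3 RPKM settings (adjusted p from 0.21 to 0.84).

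In exponential phase, engA (991377 to 992840), which encodes a GTPase of ribosome assembly, had the largest difference among coding genes. It rose 185-fold, from a normalised read count of 40.8 ± 5.09 to 7540 ± 1640 (log2 fold change 7.53 ± 0.32). The acetoin gene acoC was 122-fold higher (6.93 ± 0.40), and the regulator gene acoR was 57.6-fold higher (5.85 ± 0.28). Without wt_exponential replicate 1 the fold was 69.8 for acoC and 46.1 for PP_2342, and without wt_exponential replicate 2 it was 210 for acoC. The cell division gene ftsQ was 65.2-fold higher (6.03 ± 0.29) and phaE, a phenylacetate-CoA ligase by its annotation, 75.8-fold higher (6.24 ± 0.37). The pili assembly chaperone PP_1890 was 112-fold higher, PP_2342 was 72-fold, PP_2666 was 64.3-fold and the regulator PP_2177 was 58.1-fold higher. PP_2675, a cytochrome c-type protein, had 169 counts against 1, a ratio of 159 (95% interval 28.1 to 6310), or 54.3 (9.61 to 2160) without wt_exponential replicate 1 and at least 34.9-fold without wt_exponential replicate 2.

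Among noncoding RNAs of exponential phase, Pit247 (81212 to 81316) was 360-fold higher (8.49 ± 0.29). Against no wild-type counts, 5UTR_62 was at least 78.1-fold higher, Pit320 at least 67.4-fold, and 5UTR_58 at least 46.1-fold. The predicted RNAs at 3053908 to 3053932, 64900 to 64916 and 2977008 to 2977025 were at least 49.2-fold, 41.4-fold and 28.8-fold higher. Pat314 had a ratio of 689 (95% interval 123 to 27300), Pat339 of 440 (78.6 to 17400) and Pit046 of 426 (76.1 to 16900). Without wt_exponential replicate 1 the bounds became 0.342 times as large, and Pat314 and Pit046 were at least 78.5-fold and 48.5-fold higher while the ratio of Pat339 was 150 (26.9 to 5950). Without wt_exponential replicate 2 the bounds became 0.658 times as large, the ratios of Pat314 and Pit046 were 454 (81.2 to 18000) and 281 (50.1 to 11100), and Pat339 was at least 96.6-fold higher. At the other end, the predicted RNAs at 1126545 to 1126603 and 1433120 to 1433133 were at least 9.57-fold and 8.86-fold lower in KL3. These became 0.419 times as large without KL3_exponential replicate 1 and 0.581 times without KL3_exponential replicate 2, and the first was 5.19 without wt_exponential replicate 1. Pat275 had a ratio of 0.0132 (95% interval 0.00159 to 0.0487), Pit273 stood at -5.98 ± 0.36 and the predicted RNA at 4013557 to 4013593 at -5.90 ± 0.42. Without KL3_exponential replicate 1 Pat275 was at least 21.1-fold lower and the other 2 stood at -6.57 each, and without KL3_exponential replicate 2 the ratio of Pat275 was 0.0228 (0.00273 to 0.0839).

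Targets of catabolite repression rose as a list in exponential phase. Of 23 tested, 13 were higher and 1 lower, over all features and adjusted over the list alone (median 1.14, camera adjusted p = 0.017, adjusted p = 0.26 with an estimated correlation). The phenylalanine and homogentisate catabolic genes phhA (4.05 ± 0.27), phhB (3.89 ± 0.26) and hmgA (3.55 ± 0.38) led it. With library totals 7 were higher and 5 lower. In all, 1590 of 6336 features were higher and 1306 lower in exponential phase (edgeR, adjusted p under 0.05), against 935 and 3009 with library totals, so the higher share of calls was 54.9% and 23.7%. All 935 were also among the 1590. The count of lower features was 848 without wt_exponential replicate 1, 851 without KL3_exponential replicate 1 and 823 without KL3_exponential replicate 2. By kind, 98 of 122 5′ UTRs were higher and 11 lower, 148 and 55 of 296 intergenic small RNAs, 66 and 49 of 185 antisense small RNAs, 1087 and 919 of 4871 coding genes, 191 and 266 of 855 predicted RNAs of under 1000 bases, and 0 and 6 of the 7 longer ones.

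In transition phase the pili assembly chaperone PP_1890 (2132229 to 2133008) led the coding genes, 261-fold higher (8.03 ± 0.39), from a normalised read count of 0.906 ± 0.444 to 248 ± 109. The GntR-family regulator PP_0620 was 184-fold higher (7.52 ± 0.44) and PP_1742 was 162-fold higher (7.34 ± 0.51). The chemotaxis transducer PP_2861 was 66.0-fold higher, the regulator PP_3730 was 59.6-fold and the transporter subunit PP_4867 was 59.3-fold higher. PP_1149, 66.5-fold higher, lies wholly within PhrS. Without wt_transition replicate 1 the fold of PP_1890 was 406, without wt_transition replicate 2 that of PP_1742 was 280, and that of PP_2861 was 29.8 without KL3_transition replicate 1 and 101 without KL3_transition replicate 2. PP_4317 had 34 counts against 1, a ratio of 108 (95% interval 18.0 to 4370). Against no wild-type counts the amidase PP_2269 was at least 16.9-fold higher and the DNA primase/helicase PP_2270 at least 9.49-fold. Without wt_transition replicate 1 these bounds became 0.436 times as large and PP_4317 was at least 15.6-fold higher, and without wt_transition replicate 2 they became 0.564 times as large and the ratio of PP_4317 was 60.6 (10.2 to 2460). PP_2270 was lost without KL3_transition replicate 1 (adjusted p = 0.081), where its 2 counts allow no bound, and with log2(RPKM + 1) or log2(RPKM + 0.1) (0.00, adjusted p = 1 in each).

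Among noncoding RNAs of transition phase, 5UTR_49 was 331-fold higher (8.37 ± 0.34). The predicted RNA at 725897 to 725944, next to PP_0620, rose by 8.08 ± 0.45, and that at 3264544 to 3264680, directly upstream of PP_2861, by 7.89 ± 0.49. The former was 7.38 without wt_transition replicate 1 and 9.15 without wt_transition replicate 2, and the latter 6.87 without KL3_transition replicate 1. Pit320 was at least 273-fold higher, 5UTR_58 at least 123-fold and Pat314 at least 31.6-fold, but without KL3_transition replicate 1 the first 2 fell to 94.3-fold and 56.6-fold. The predicted RNAs at 64900 to 64916, 3086615 to 3086648 and 2977008 to 2977025 were at least 58.0-fold, 32.7-fold and 28.5-fold higher, the last being 18.9-fold without KL3_transition replicate 1, and Pat259 had a ratio of 471 (95% interval 83.3 to 18700). Without wt_transition replicate 1 the 6 bounds became 0.436 times as large and Pat259 was at least 68.5-fold higher, and without wt_transition replicate 2 they became 0.564 times as large and the ratio of Pat259 was 266 (47.0 to 10600). P32 was at least 8.86-fold lower and Pat321 at least 6.85-fold lower. The predicted RNAs at 3515728 to 3515797, 1433120 to 1433133 and 2150642 to 2150675 were at least 8.75-fold, 8.01-fold and 7.59-fold lower. These 5 became 0.391 times as large without KL3_transition replicate 1 and 0.609 times without KL3_transition replicate 2.

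Ribosomal protein mRNAs fell relative to the typical feature in transition phase. Of 53, 39 were lower and 5 higher over all features, and 39 and 6 adjusted over the list alone (median -1.11, camera adjusted p = 0.0012, adjusted p = 0.87 with an estimated correlation). Examples are rpsD (-2.22 ± 0.28), rplS (-2.09 ± 0.33) and rplQ (-1.94 ± 0.26). With library totals 51 were lower and 0 higher, beside a median of all features of -2.05. In all, 1543 features were higher and 1741 lower in transition phase, against 452 and 5055 with library totals (47.0% and 8.2% of calls higher), and all 452 were among the 1543. By kind, 98 of 122 5′ UTRs were higher and 6 lower, 160 and 56 of 296 intergenic small RNAs, 82 and 39 of 185 antisense small RNAs, 1021 and 1332 of 4871 coding genes, 182 and 302 of 855 predicted RNAs of under 1000 bases, and 0 and 6 of the 7 longer ones.

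In stationary phase the cell division genes ftsQ (1526772 to 1527641) and ftsA were 174-fold (7.44 ± 0.31) and 139-fold higher (7.11 ± 0.31). The normalised read count of ftsQ went from 59.3 ± 8.06 to 10300 ± 657. The GTPase gene engA was 104-fold higher, PP_2342 was 64.2-fold, PP_1149 within PhrS was 45.9-fold and acoC was 42.0-fold higher. Without wt_stationary replicate 1 the fold of PP_2342 was 110 and that of acoC 24, and without wt_stationary replicate 2 that of acoC was 75.5. PP_0556, annotated as an AcoX kinase, had 272 counts against 2, a ratio of 126 (95% interval 34.7 to 1050), and PP_2855 had 98 against 2, a ratio of 45.6 (12.3 to 382). Without wt_stationary replicate 1 the ratio of PP_0556 was 44.6 (12.2 to 370) and PP_2855 was at least 10.7-fold higher, and without wt_stationary replicate 2 PP_0556 was at least 54.6-fold higher and the ratio of PP_2855 was 29.5 (7.96 to 247). PP_2269 and PP_4317 were at least 7.75-fold and 7.44-fold higher, bounds that became 0.352 times as large without wt_stationary replicate 1 and 0.648 times without wt_stationary replicate 2, and PP_4317 was at least 3.68-fold higher without KL3_stationary replicate 1.

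Among noncoding RNAs of stationary phase, Pit247 was 209-fold higher (7.71 ± 0.31), and Pat314 had a ratio of 352 (95% interval 62.7 to 13900). Pit320 and 5UTR_22 were each at least 18.9-fold higher and Pit312 at least 12.7-fold. The predicted RNAs at 5325522 to 5325535, 64900 to 64916 and 2977008 to 2977025 were at least 15.5-fold, 14.9-fold and 13.0-fold higher, and those at 2318923 to 2318935 and 861833 to 861843 at least 11.2-fold. Without wt_stationary replicate 1 these 8 bounds became 0.352 times as large and Pat314 was at least 41.3-fold higher, and without wt_stationary replicate 2 they became 0.648 times as large and the ratio of Pat314 was 228 (40.6 to 9020). The predicted RNAs at 2081123 to 2081157, 2826979 to 2826996, 1380413 to 1380431 and 1433120 to 1433133 were at least 14.7-fold, 7.17-fold, 6.45-fold and 5.38-fold lower. These became 0.421 times as large without KL3_stationary replicate 1 and 0.579 times without KL3_stationary replicate 2, and the third had 3 counts without wt_stationary replicate 1, which allow no bound. The predicted RNA at 6104713 to 6104759, antisense to PP_5355, had a ratio of 0.00869 (95% interval 0.000218 to 0.0495), or 0.0207 (0.000518 to 0.118) without KL3_stationary replicate 1, and was at least 22.2-fold lower without KL3_stationary replicate 2.

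Stress genes were higher in KL3 than in the wild type as a list in stationary phase. Of 16, 10 were higher and 0 lower, over all features and adjusted over the list alone (median 1.33, camera adjusted p = 0.0046, adjusted p = 0.28 with an estimated correlation). The chaperone genes groES (4.12 ± 0.27), dnaK (2.94 ± 0.27) and groEL (2.72 ± 0.24) led it. The normalised read count of groEL in KL3 was 311 ± 41.5, below its 600 ± 5.72 in exponential phase. In the wild type it was 47.5 ± 10.5, below 440 ± 60.2 in exponential phase. The difference of groEL thus came with a lower wild-type level, not with a higher KL3 level. With library totals 5 of the 16 stress genes were higher and 5 lower. In all, 1336 features were higher and 1390 lower in stationary phase, against 542 and 4205 with library totals (49.0% and 11.4% of calls higher), and all 542 were among the 1336. By kind, 91 of 122 5′ UTRs were higher and 8 lower, 142 and 63 of 296 intergenic small RNAs, 55 and 54 of 185 antisense small RNAs, 908 and 930 of 4871 coding genes, 140 and 334 of 855 predicted RNAs of under 1000 bases, and 0 and 1 of the 7 longer ones.

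Many of these differences recurred in each phase. Pit247 averaged 7.88 ± 0.17 over the phases, engA 6.64 ± 0.18, PhrS 5.75 ± 0.18 and CrcZ 3.95 ± 0.15, while Pit273 averaged -5.72 ± 0.19. Of all features, 882 were higher in all 3 phases, where 82 would be by chance, and 556 were lower in all 3, where 79 would be. With library totals 452 features were higher in transition phase, so no more than these could be higher in all 3. The 882 held 514 coding genes, 123 intergenic and 51 antisense small RNAs, 88 5′ UTRs and 106 predicted RNAs. The average over phases called 1854 features higher and 2295 lower, against 723 and 4927 with library totals (44.7% and 12.8% of calls higher).

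Some differences depended on the growth phase. PP_0620 rose by 3.37 ± 0.37, 7.52 ± 0.44 and 1.26 ± 0.38 in exponential, transition and stationary phase, and PP_0354 stood at -0.28 ± 0.28, 4.39 ± 0.29 and -0.72 ± 0.40. The xanthine dehydrogenase gene xdhA rose by 5.49 ± 0.29, 2.59 ± 0.25 and 1.24 ± 0.24, and the sugar transporter gene PP_1015 by 5.84 ± 0.31, 3.25 ± 0.27 and 1.08 ± 0.29. The chaperonin gene groEL stood at 0.45 ± 0.22, -1.14 ± 0.22 and 2.72 ± 0.24, and the lysine synthesis gene dapB at 1.84 ± 0.23, -0.42 ± 0.23 and 3.87 ± 0.29. From exponential to stationary phase the normalised read count of groEL went from 440 to 47.5 in the wild type and from 600 to 311 in KL3. That of dapB went from 29.4 to 4.21 and from 105 to 57.7, so the wild type changed more for both. For PP_0620, PP_0354, xdhA and PP_1015 KL3 changed more between these 2 phases. The phase dependence of these 6 had adjusted p from 5.7e-06 to 6.8e-06, and 1475 of 6336 features passed, or 834 without KL3_transition replicate 1. In stationary phase, with library totals, PP_1015 was at -0.07, xdhA at 0.08 (adjusted p = 0.80) and PP_0620 at 0.12 (adjusted p = 0.76), and these 3 calls were also lost in the 3 RPKM settings (adjusted p from 0.62 to 0.90). With library totals 3156 features passed, dapB was lower in transition phase (-2.30) and PP_0354 was lower in exponential (-1.02) and stationary phase (-1.88). The stationary call of PP_1015 was lost without wt_stationary replicate 1 (adjusted p = 0.12) or KL3_stationary replicate 2 (0.053), and that of PP_0620 without wt_stationary replicate 1 (0.14) or KL3_stationary replicate 1 (0.24).

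Within KL3, RNA level and binding are mixed. From exponential to transition phase the transporter genes PP_0617, PP_0615 and PP_0618 rose most. PP_0617 went from 3 to 552 counts, a ratio of 451 (95% interval 153 to 2190), PP_0615 had a ratio of 391 (107 to 3240), and PP_0618 was 344-fold higher. PP_0556 was 237-fold higher, and the electron transfer gene PP_0313 had a ratio of 279 (49.1 to 11100). Without KL3_exponential replicate 1 the ratio of PP_0615 was 164 (44.9 to 1360) and PP_0313 was at least 39.0-fold higher. Without KL3_exponential replicate 2 PP_0615 was at least 151-fold higher, the ratio of PP_0313 was 162 (28.6 to 6470) and that of PP_0618 was 531 (181 to 2580). Without KL3_transition replicate 2 the fold of PP_0556 was 126. Against no counts in transition phase, PP_0277, PP_1824 and the nuclease gene PP_5086 were at least 5.31-fold, 4.35-fold and 3.54-fold lower. PP_0945 and PP_3143 were at least 3.40-fold and 2.86-fold lower, but both were lost without KL3_transition replicate 1 (adjusted p = 0.088 and 0.096), with log2(RPKM + 1) (-1.29 and -0.50, adjusted p = 0.068 and 0.40) and with RPKM of at least 1 in 2 libraries (adjusted p = 0.053 and 0.37). PP_3143 was also lost with log2(RPKM + 0.1) (-1.73, adjusted p = 0.34), and was at least 1.87-fold lower without KL3_exponential replicate 2. These 5 bounds became 0.391 times as large without KL3_transition replicate 1 and 0.609 times without KL3_transition replicate 2. From exponential to stationary phase the oxidoreductase gene PP_4037 was 329-fold higher, PP_3597 was 195-fold, PP_3596 was 156-fold, PP_2656 was 93.0-fold and PP_3449, which shares 15.5% of its bases with PP_3450, at least 21.5-fold higher, or 9.02-fold and 12.5-fold without KL3_exponential replicate 1 or 2. Without KL3_stationary replicate 2 the fold of PP_2656 was 60.7, and without KL3_stationary replicate 1 the ratio of PP_2920 was 0.00835 (0.000211 to 0.0468). The lowest were PP_1015 (-7.35 ± 0.33), PP_2920 (-5.50 ± 0.47), phhA (-5.00 ± 0.28), zwf-1 (-4.90 ± 0.33) and rplD (-4.76 ± 0.34). On the log2 scale the same change in the wild type was 5.74 for PP_0617, beside 8.79 in KL3, and 7.16 for PP_4037, beside 8.36. It was -2.65 for PP_1015, beside -7.35, and -4.36 for rplD, beside -4.76. Features higher and lower numbered 1511 and 1795 in transition phase, against 725 and 2758 with library totals (45.7% and 20.8% of calls higher), and 1761 and 2138 in stationary phase.

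The authors' deposited q-values give a list made on these very libraries, so the overlap is not independent evidence. Under 0.05 in all 4 pairs of a phase were 72, 58 and 62 features in exponential, transition and stationary phase. All were called here as well, where 33, 30 and 27 would be by chance, and 43, 35 and 38 of them were higher in KL3.

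Genes of amino acid transport, respiration and the cell surface did not pass as lists. Amino acid transport had 24 of 83 members higher and 11 lower in stationary phase, 24 and 11 adjusted over the list alone (adjusted p = 0.074), with PP_3597 at 4.66 ± 0.35, or 5.37 without wt_stationary replicate 1, and PP_0282 at 4.43 ± 0.26. Porins had 17 of 43 higher and 8 lower in stationary phase, 17 and 8 adjusted over the list alone (adjusted p = 0.095), with PP_0045 at 3.93 ± 0.50 and PP_3390 at 3.22 ± 0.53. Without wt_stationary replicate 1 PP_0045 was at least 9.17-fold higher and PP_3390 at 2.44, and without wt_stationary replicate 2 PP_0045 was at 3.31 and PP_3390 had a ratio of 16.9 (5.58 to 83.4). The call for PP_3390 was lost with log2(RPKM + 0.1) (adjusted p = 0.13). ATP synthase had 8 of 9 lower and 1 higher in transition phase, also adjusted over the list alone (adjusted p = 0.055), with atpG at -1.96 ± 0.26 and atpA at -1.92 ± 0.26. It passed without wt_transition replicate 2 (0.013), KL3_transition replicate 2 (0.040), KL3_stationary replicate 1 (0.044) or KL3_stationary replicate 2 (0.049). NADH dehydrogenase had 6 of 12 lower and 1 higher in transition phase, 7 and 1 adjusted over the list alone (adjusted p = 0.20), with nuoE at -2.22 ± 0.32. Its member nuoJ (-1.31 ± 0.42) was lost with only the 4 libraries of the phase (0.064) and without wt_transition replicate 1 (0.11) or KL3_transition replicate 2 (-0.72, 0.13), and had a ratio of 0.104 (0.0124 to 0.381) without KL3_transition replicate 1. Terminal oxidases had 9 of 19 higher and 1 lower in exponential phase, also adjusted over the list alone (adjusted p = 0.11), with ccoQ-2 at 4.62 ± 0.36 and ccoN-2 at 2.10 ± 0.25.

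The remaining lists did not pass in the phases given here either. Flagella and chemotaxis had 25 of 83 higher and 12 lower in exponential phase, 24 and 12 adjusted over the list alone (adjusted p = 0.64), with PP_2861 at 4.84 ± 0.45 and the CheW gene PP_4987 at -2.76 ± 0.57. The TCA cycle had 5 of 18 higher and 2 lower in exponential phase, also adjusted over the list alone (adjusted p = 0.64), with lpdG at 2.26 ± 0.25 and sdhA at 1.70 ± 0.27. Iron genes had 15 of 40 higher and 6 lower in exponential phase, also adjusted over the list alone (median -0.03, mean 0.30, adjusted p = 0.64), with the siderophore receptors fpvA at 3.44 ± 0.33 and PP_2420 at 3.03 ± 0.29. Cold shock genes had 3 of 3 higher in exponential phase, also adjusted over the list alone (adjusted p = 0.099), with cspA-2 at 2.07 ± 0.22 and cspA-1 at 1.61 ± 0.25. Polyhydroxyalkanoate had 6 of 13 lower and 2 higher in transition phase, also adjusted over the list alone (adjusted p = 0.44), with phaH at -3.26 ± 0.45 and phaB at -2.69 ± 0.39. By their products phaH encodes a phenylacetate-CoA oxygenase subunit and phaB an enoyl-CoA hydratase, so the list, made by gene name, is not of polyhydroxyalkanoate genes alone. Transposases had 20 of 51 higher and 6 lower in transition phase, also adjusted over the list alone (adjusted p = 0.086), with PP_0014 at 2.75 ± 0.31 and PP_2976 at 2.43 ± 0.32, the latter lost with library totals (0.57, adjusted p = 0.12) and in the 3 RPKM settings (adjusted p from 0.091 to 0.099). Regulators had 89 of 352 higher and 75 lower in transition phase, 88 and 72 adjusted over the list alone (adjusted p = 0.64). In stationary phase catabolite repression targets had 12 higher and 3 lower, 13 and 3 adjusted over the list alone (adjusted p = 0.055), and passed without KL3_stationary replicate 1 (0.033), wt_transition replicate 1 (0.042), wt_transition replicate 2 (0.045), KL3_transition replicate 2 (0.049) or KL3_exponential replicate 2 (0.049), and with library totals (0.026). Stress genes in transition phase had 9 lower and 1 higher (adjusted p = 0.095) and passed without wt_transition replicate 1 (0.036). In all, 8 of 51 list tests passed with camera, and 0 with an estimated correlation.

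**Figure D3:**
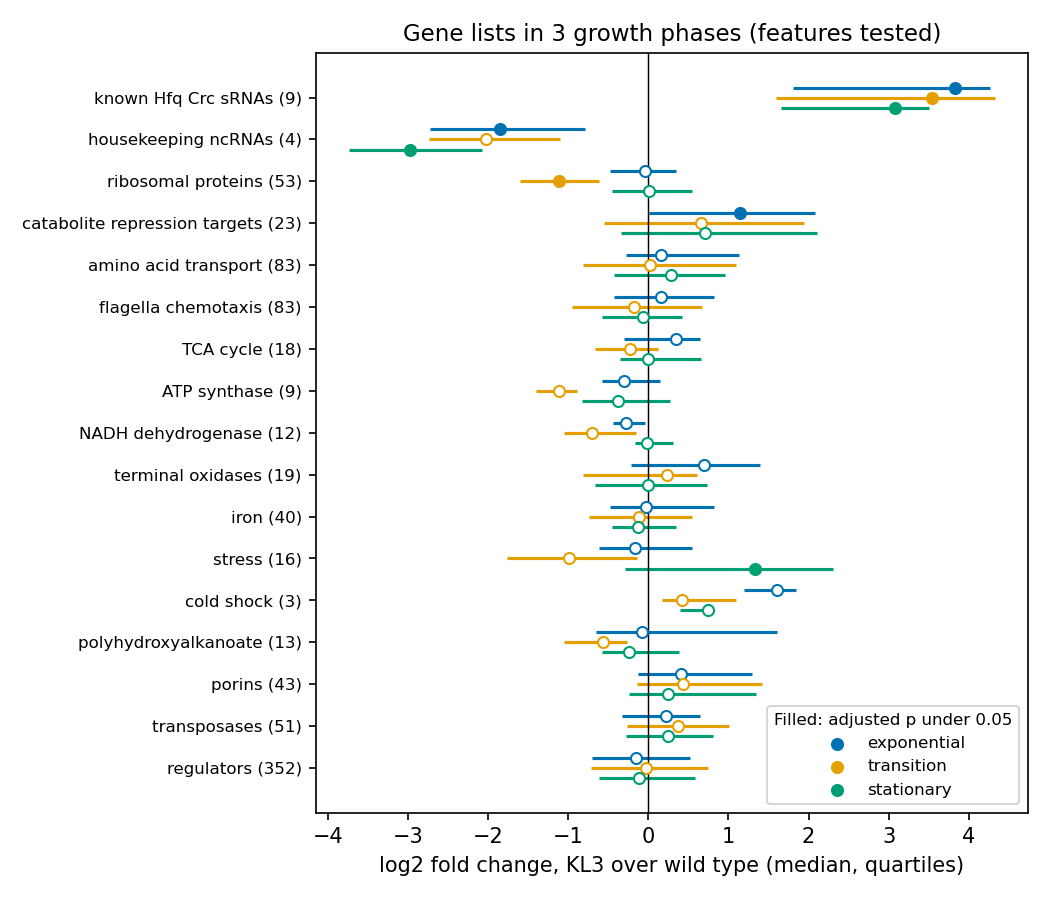
Median log2 fold change of KL3 over wild type for each gene list and phase, with lines from the lower to the upper quartile, and filled points where camera passed. Known small RNAs have medians of 3.83, 3.54 and 3.08, and ribosomal proteins -1.11 in transition phase.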

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

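The tests of direction and of wild-type RNA levels were set before their results were seen. The tests of factors per group, of overlap, of PP_1149 and of the long RNAs were chosen after.

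The difference between KL3 and wild type changed with the growth phase for 1475 features by a test of the difference itself, and for 3156 with library totals. Of the 1475, 32.3% were larger in transition than in exponential phase, which decides nothing about scaling, since TMM centres the differences near 0. Under 161 pairs of factors for the KL3 libraries of the 2 later phases (log2 from -2 to 2), at least 1354 features passed, or 91.8% of the count reported, so 1 wrong factor per group does not account for the pattern as a whole, though the number depends on the scaling. Were the wild-type RNA level the source, the wild-type libraries would change more than KL3 in most of them, but they did so in 32.9%. These changes were taken on log2(CPM + 1), which shrinks them where the wild-type CPM is near or below 1. The comparison therefore cannot decide about the wild-type RNA level for these features as a set. For groEL and dapB, with mean wild-type CPM from 4.21 to 720, the wild type changed more than KL3 from exponential to stationary phase. Phase-specific binding by Hfq may contribute, but is a hypothesis found and tested on the same data, and RNA level and binding in KL3 were not separated.

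The coding genes with the largest differences could gain reads from an overlapping feature of their strand. Of 22 such genes, 4.5% (PP_1149) share at least 10% of their bases with another feature, against 0.3% of all tested coding genes, which argues against this as the source for most of them. For PP_1149, which lies wholly within PhrS, the values are those that shared reads predict. The ratio of its counts to those of PhrS varied by 1.02 times (0.568 to 0.579) over the 12 libraries, while PhrS counts varied 252-fold. Its difference therefore cannot be told apart from that of PhrS and is no evidence for a separate enriched mRNA.

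The 7 long predicted RNAs that took most wild-type counts may be copies of 1 repeated operon, such as an rRNA operon. The feature at 171070 to 181794 had 1.90 to 2.02 times the mean counts of 4 features of about 5 kb in each library, as a pair of copies would. The genome sequence was not used here, so their identity was not tested.

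The phase dependence also passed for named features, with adjusted p from 5.7e-06 to 0.048. These were PP_0354 (5.7e-06), PP_0620, xdhA, PP_1015 and groEL (6e-06 each), dapB (6.8e-06), groES (7.5e-06), acoC and PP_2177 (2.3e-05 each), ftsA (2.4e-05), ftsQ (4e-05), dnaK (5e-05), phaE (9.5e-05), PP_2861 and phhA (0.00011 each), PP_1742 (0.0003), RsmZ (0.00031) and phhB (0.00057). They were followed by PP_3597 and fpvA (0.0011 each), 5UTR_49 (0.0025), RgsA/P16 (0.0031), PP_0045 (0.0032), the predicted RNA at 3264544 to 3264680 (0.0035), PP_0618 (0.0037), engA (0.0041), acoR (0.0045), Psr2/CrcX (0.0064), PP_3730 (0.0068), rplD (0.008), cspA-1 (0.0082), PP_1824 (0.0091), sdhA (0.0092) and PP_3596 (0.0093). The rest were hfq and Prrf2 (0.013 each), PP_1890 (0.014), cspA-2 (0.016), rpsD (0.017), SRP (0.023), SsrA_tmRNA (0.024), rplQ (0.025), PP_2675 and Pat321 (0.026 each), atpA (0.028), PP_2666 and Pit312 (0.03 each), the predicted RNA at 725897 to 725944 (0.034), PP_4037 and atpG (0.044 each) and ccoQ-2 (0.048).

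Of 34 tests of lists between phases, 8 passed with the preset correlation. From exponential to transition phase the median difference was -1.08 for ribosomal proteins (adjusted p = 3.1e-06, adjusted p = 0.61 with an estimated correlation), -1.18 for ATP synthase (0.017, and 0.61), -0.81 for terminal oxidases (0.039, and 0.50), -1.09 for stress (0.033, and 0.50), -1.54 for the list named polyhydroxyalkanoate, which also holds phenylacetate genes (0.011, and 0.50), and 0.32 for transposases (0.032, and 0.50). From exponential to stationary phase it was -1.24 for housekeeping RNAs (0.026, and 0.50) and 1.60 for stress (3.4e-09, and 0.13).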

How the results depend on the processing

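The alternatives without long or predicted RNAs, without overlapping features or members, and with the other share denominator were chosen after the data were seen. With any single library left out, 236 of 240 counts and shares, 2265 of 2279 values of named features and 597 of 612 list tests held. They kept their side of the threshold and, where called, their direction, and no called one reversed. The sign of named values that were not called was not scored. RnpB/P28 in transition phase, not called, went from -0.34 to 0.38 without wt_transition replicate 2. A group left with 1 library is assumed to vary like the others. Under the other alternatives 143 of 186, 2125 of 2212 and 217 of 255 held. Higher and lower counts were 935 and 3009 (exponential), 452 and 5055 (transition), 542 and 4205 (stationary) and 723 and 4927 (average) with library totals, and 3156 features depended on the phase. With log2(RPKM + 1) they were 953 and 2184, 444 and 4762, 572 and 3823, 772 and 4754, and 2915. With log2(RPKM + 0.1) they were 929 and 2017, 417 and 4650, 530 and 3363, 761 and 4649, and 2804. With RPKM of at least 1 in 2 libraries they were 965 and 2262, 451 and 4810, 589 and 3891, 777 and 4800, and 3051. A 2-fold minimum, stricter by construction, left 850 lower in exponential phase, and 1127 higher and 1069 lower on average. Leaving out a library gave 823 to 1362 lower in exponential phase and 834 to 1604 with phase dependence. Without the 7 long RNAs in the denominator the coding share was -33.8 and the other predicted RNAs -3.09. In transition phase log2 fold changes reversed for rpoS (-0.221 with library totals; -0.113, -0.114 and -0.113 with RPKM), RsmY (-0.287; -0.185 in all 3 RPKM settings), Prrf2 (-0.488; -0.318, -0.319 and -0.318) and Spot42-like/spf/ErsA (-0.103 with library totals), and in stationary phase with library totals for rpoS (-0.0245) and PP_1015 (-0.0678). List tests passed 0 times with an estimated correlation and 33 times with fry, which turned regulators in exponential phase upward (adjusted p = 0.0131). For these changes and reversals the cause was not tested. With the replicate number as a block, 1473 features depended on the phase and 8 lists passed; with the culture within a strain as a block, 1580 did, and 3353 and 3959 features changed within KL3 in transition and stationary phase. Neither block moved a named result that it was run on across the threshold. Over 3609 features, replicate differences of the 2 strains had correlations of -0.02, -0.01 and -0.03 in the same phase. Between other groups they ran from -0.23 (wild type in transition and KL3 in stationary phase) to 0.20 (KL3 in transition and stationary phase), with 0.19 for the wild type in exponential and stationary phase, so a pairing of strains within phases is not seen and shared cultures within a strain stay open.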

Other observations

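Translation genes as a class were lower in KL3 in transition phase. Functional categories were tested only after the data were seen. Of 185 tested genes of category J (translation), 102 were lower and 21 higher (median -0.93, adjusted p = 0.0051 over 60 tests), and of 90 of category F (nucleotide metabolism), 44 were lower and 11 higher (median -0.90, adjusted p = 0.029). Both had adjusted p = 0.98 with an estimated correlation. Ribosomal protein genes, reported above as lower in this phase, are translation genes, so category J is not a separate result. The genes shared by the list and the category were not counted.

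The 5′ UTRs rose more than the genes that follow them. Over 100 pairs the median log2 fold change was 3.12 for the UTR and 0.42 for the gene in exponential phase, and the median difference was 2.29, against 2.78 in transition phase and 2.41 in stationary phase. Of the UTRs, 82 were higher in exponential phase, and in 38 pairs the gene was too. Enrichment of the whole transcript, read evenly along its length, would put the difference near 0, which was not seen. A small RNA library made without fragmentation can favour short RNAs, so reads need not be even. The test therefore cannot exclude enrichment of the whole transcript. Binding or stability of the UTR alone may also explain the difference and was not tested.

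The real grouping called 4149 features on average over phases. Of 100 splits within phases, drawn from 108 possible, 1, the real one, called as many, which is the fewest possible, and the highest other called 2094. Every other split puts libraries of both strains in 1 group, which widens the spread and lowers the calls. The comparison therefore shows only that these libraries group by strain, and it cannot exclude chance. Chance between cultures is not covered, since no label says that the libraries of a group came from separate cultures.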
